A study of Homo sapiens with 9 samples.

How the data were processed

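RNA-seq values of OCM1, a human ocular melanoma cell line, were analysed in 9 libraries, 3 from each of the groups sgRNA-NC, sgRNA-1 and sgRNA-2. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates are separate cultures, so the p-values then measure only the spread between these samples. Nor do they say whether the guide cells are clones or pools, so a difference between guide and control libraries may be one between cell populations rather than an effect of the deletion. Per the labels' protocols, total RNA was extracted with Trizol and made into TruSeq libraries, and the values were placed on the hg19 build. The aligner and the quantifier are not given in the sources used here. The protocol text of the replicate 1 libraries differs from that of replicates 2 and 3, and speaks of tissue samples. Replicate 1 was therefore treated as a possible batch, which crosses all 3 groups.

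The authors deposited 2 transcript tables, each setting a guide beside the control, with 31455 transcripts for sgRNA-1 and 31532 for sgRNA-2. Per the file headers, each library column holds FPKM, fragments normalized to transcript length and library size, computed by the authors for each library. The listed transcripts are of the protein-coding type in both tables, and each has a mean of at least 0.5 FPKM in the larger group. Per the file headers the group columns are FPKM, but they equal the mean of log2(FPKM + 1) over a group. The deposited log2 fold change is the difference of these means, guide minus control, and the deposited fold change is the same ratio on the linear scale. The deposited p-value equals that of an equal-variance statistic on log2(FPKM + 1), with a largest difference of 1.6e-10. The deposited q-value is a Benjamini-Hochberg adjustment over more transcripts than are listed (55128 and 55792 implied). The control columns are identical in both tables, with a largest difference of 0. For this work 2 lines of each were emptied, and the genes on them were not analysed here. Sequencing depth is not given by FPKM, so no interval or floor that needs depth is reported.

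A gene's value is the sum of FPKM over its listed transcripts. Of 33031 transcripts in either table, 29956 are in both. A transcript in 1 table only has a mean under 0.5 FPKM in the control. Its values for the other guide are not listed and were set to 0. That its mean there is also under 0.5 FPKM was inferred from the limit of the listing. This handling was chosen after seeing the data. Of 11722 genes, 11063 had at least 1 FPKM in at least 3 libraries and were tested. Among these, 2314 hold a transcript listed in 1 table only, and 7 consist of such transcripts. Sums cover listed protein-coding transcripts only, and an exact 0 can be a failed estimate. Reads of near-identical copies, such as HSPA1A and HSPA1B, the tubulin genes and the HLA genes, or of overlapping genes may have been split by the quantifier, so the values of such genes are uncertain.

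Tests used limma 3.58.1 in R 4.3.3 (data.table version 1.17.8) on log2(FPKM + 1), with an empirical Bayes trend and robust variances. A single fit held all 9 libraries and left 6 residual degrees of freedom. Its contrasts were sgRNA-1 against sgRNA-NC, sgRNA-2 against sgRNA-NC, sgRNA-2 against sgRNA-1, and the mean of both guides against sgRNA-NC. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 11063 genes, with a threshold of 0.05. Every adjusted p of a gene comes from this limma fit, unless an alternative is named beside it. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Of a gene whose libraries in a group are all at 0, no fold is given, except for MB, whose difference between the guides stands beside its value with missing transcripts at 0.5 FPKM.

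Genes were named by a fixed rule. In each contrast it took the 10 largest positive and the 10 largest negative log2 fold changes among called genes with a mean of at least 1 FPKM in a group and no overlap between the groups' libraries. It added the tested genes near the deletion and of the neurotensin list, and up to 4 called members with the largest changes of each gene list. Other named genes are said to have been chosen after their values were seen. Lists of 33 gene groups were fixed in advance, and the 24 with at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, and again with an estimated correlation. List p-values were adjusted over these 24 lists. Counts adjusted over the list alone stand beside those over all genes tested. For genes near the deletion, exact two-sided permutation tests were run per guide, and with 3 against 3 libraries their smallest p is 0.1.

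The overlap of both guides was set beside 100 simulated draws of unchanged groups with shared controls. The limma fit was tested on simulated log2 values of 11063 genes, with independent normal noise and 50 genes changed by each fold. In the comparison of sgRNA-1 with sgRNA-NC it called 58% of genes changed by 1.5-fold, 84% at 2-fold, 92% at 4-fold and 100% at 8-fold, and 4.57% of calls were false. For sgRNA-2 against sgRNA-NC the shares were 58%, 78%, 98% and 100%, with 6.70% false calls. For sgRNA-2 against sgRNA-1 they were 56%, 78%, 92% and 98%, with 6.90% false calls, and for both guides 56%, 88%, 94% and 98%, with 6.67%. The sums over transcripts, the filling of missing values and the filter were not simulated. Far fewer genes changed in the simulation than were called in the comparisons with sgRNA-NC, so these shares need not carry over to them.

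Alternatives covered other pseudocounts and filters, transcripts in place of genes, rescaled and quantile-normalized values, a replicate block, a batch term for replicate 1, fewer libraries, other limma settings and the deposited q-values. Rescaled values summed to 1e+06 per library, and the filter and the pseudocount stayed at 1 on that larger scale. Every library was also left out in turn. Later additions were sums over shared transcripts only, missing values at 0.5 FPKM, and fits without chromosomes 10, 13 and 18 or without genes holding a transcript in 1 table only. Groups, contrasts, tests, gene lists, the naming rule and the other alternatives were fixed before the data were examined. Positions and exons come from the hg19 annotation, in which 97.1% of transcripts were found by identifier, 62.7% of those at the same coordinates. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.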

Results

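The transcripts of OCM1 ocular melanoma cells were measured by RNA-seq in 9 libraries, 3 each labelled sgRNA-NC, sgRNA-1 and sgRNA-2. Per the series text, both sgRNA-1 and sgRNA-2 cells lack an enhancer in an intron of LRRIQ1 on chromosome 12. The same text also speaks of a deleted NTS promoter, and the labels do not resolve this. sgRNA-NC was taken as the control. Depth is unknown, and the listed values summed to between 293106 and 311804 FPKM per library. Across genes, which are not independent replicates, Pearson's r was 0.970 to 0.979 within groups, 0.968 to 0.975 between sgRNA-1 and sgRNA-2, and 0.933 to 0.941 between control and guide libraries. The first principal component (47.8% of the variance) separated control from guide libraries, and the next (11.9%) separated replicate 1 from replicates 2 and 3 in every group. Values are means ± SD over 3 libraries unless stated otherwise, and log2 fold changes are given with their SE.

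The deleted element and its neighbourhood were examined first, since the series asks what the element does for genes around NTS. The deletion spans 1187 bp (hg19, chromosome 12, 85469730 to 85470916), between exons 11 and 12 of LRRIQ1-202. NTS, which encodes the peptide neurotensin, and LRRIQ1 were not analysed here, so the deletion could not be checked from its own transcripts. Of 14 listed neighbours 8 were tested. TMTC2, a mannosyltransferase gene 1941 kb from the deletion, fell by 1.09 ± 0.14 on the log2 scale in both guides together (adjusted p = 5.3e-04), with 21.9 ± 3.13 FPKM in sgRNA-NC, 10.4 ± 1.95 in sgRNA-1 and 9.25 ± 1.39 in sgRNA-2. ALX1, a homeobox transcription factor gene 203 kb away, fell by 0.47 ± 0.08 (adjusted p = 0.00278), with 12.9 ± 1.05 FPKM in sgRNA-NC, 9.13 ± 0.926 in sgRNA-1 and 8.91 ± 0.613 in sgRNA-2. DUSP6, an ERK phosphatase gene 4270 kb away, rose by 0.50 ± 0.11 (adjusted p = 0.00820), with 29.6 ± 5.22 FPKM in sgRNA-NC, 44 ± 1.43 in sgRNA-1 and 40.0 ± 4.59 in sgRNA-2. In these 3 genes all guide libraries lay on the same side of all control libraries, and the exact two-sided permutation p was 0.1 for each guide, the smallest this design allows. The same 3 passed when adjusted over the list alone. Of all 11063 genes tested 38.1% were called in both guides together. The 3 of 8 neighbours called are near this share, so their number is no result about the neighbourhood. By the deposited q-values of their most abundant transcripts none was called with sgRNA-1 or sgRNA-2: TMTC2 had 0.209 and 0.133, ALX1 0.123 and 0.0733, and DUSP6 0.0965 and 0.218.

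SLC6A15, an amino acid transporter gene 162 kb from the deletion, did not pass (log2 fold change -0.23 ± 0.10, adjusted p = 0.0947), with 33.5 ± 2.99 FPKM in sgRNA-NC, 27.3 ± 2.50 in sgRNA-1 and 29.5 ± 3.83 in sgRNA-2. Its transcripts went different ways: SLC6A15-201 fell by 1.44 ± 0.20 (adjusted p = 0.00369), and the shorter SLC6A15-202 was at or near 0 in the controls and rose in both guides together (adjusted p = 0.0385), although it was listed at 0 in sgRNA-1 replicate 2 and did not pass with sgRNA-1 alone (adjusted p = 0.149). C12orf29, CEP290, TMTC3 and KITLG, which encodes the KIT ligand, did not pass either, with log2 fold changes of 0.15, -0.05, 0.12 and 0.33. SORT1, on chromosome 1, encodes the neurotensin receptor sortilin and was the only one of 5 neurotensin list genes tested. It fell by 0.51 ± 0.06 (adjusted p = 4.0e-04), with 17.4 ± 0.399 FPKM in sgRNA-NC, 11.7 ± 0.739 in sgRNA-1 and 12.1 ± 0.718 in sgRNA-2. As a list, the neighbours did not differ from other genes (camera adjusted p = 0.526), and their median (0.04) and mean (-0.09) differ in sign. For its most abundant transcript SORT1 was not called (-0.39, adjusted p = 0.0958). The rise of DUSP6 with sgRNA-2 (adjusted p = 0.0336) was not called in 9 of 26 alternatives, among them a fit of the 6 libraries compared (0.43, adjusted p = 0.0717) and fits without sgRNA-NC replicate 1 (0.0903), sgRNA-NC replicate 2 (0.0964) or sgRNA-2 replicate 2 (0.105). With sgRNA-1 DUSP6 was not called without replicate 1 of every group (0.0533), and SLC6A15 passed in both guides together without sgRNA-2 replicate 3 (0.0397). TMTC3 passed with sgRNA-2 in the fit with a batch term for replicate 1 (0.17, adjusted p = 0.0490).

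**Figure D1:**
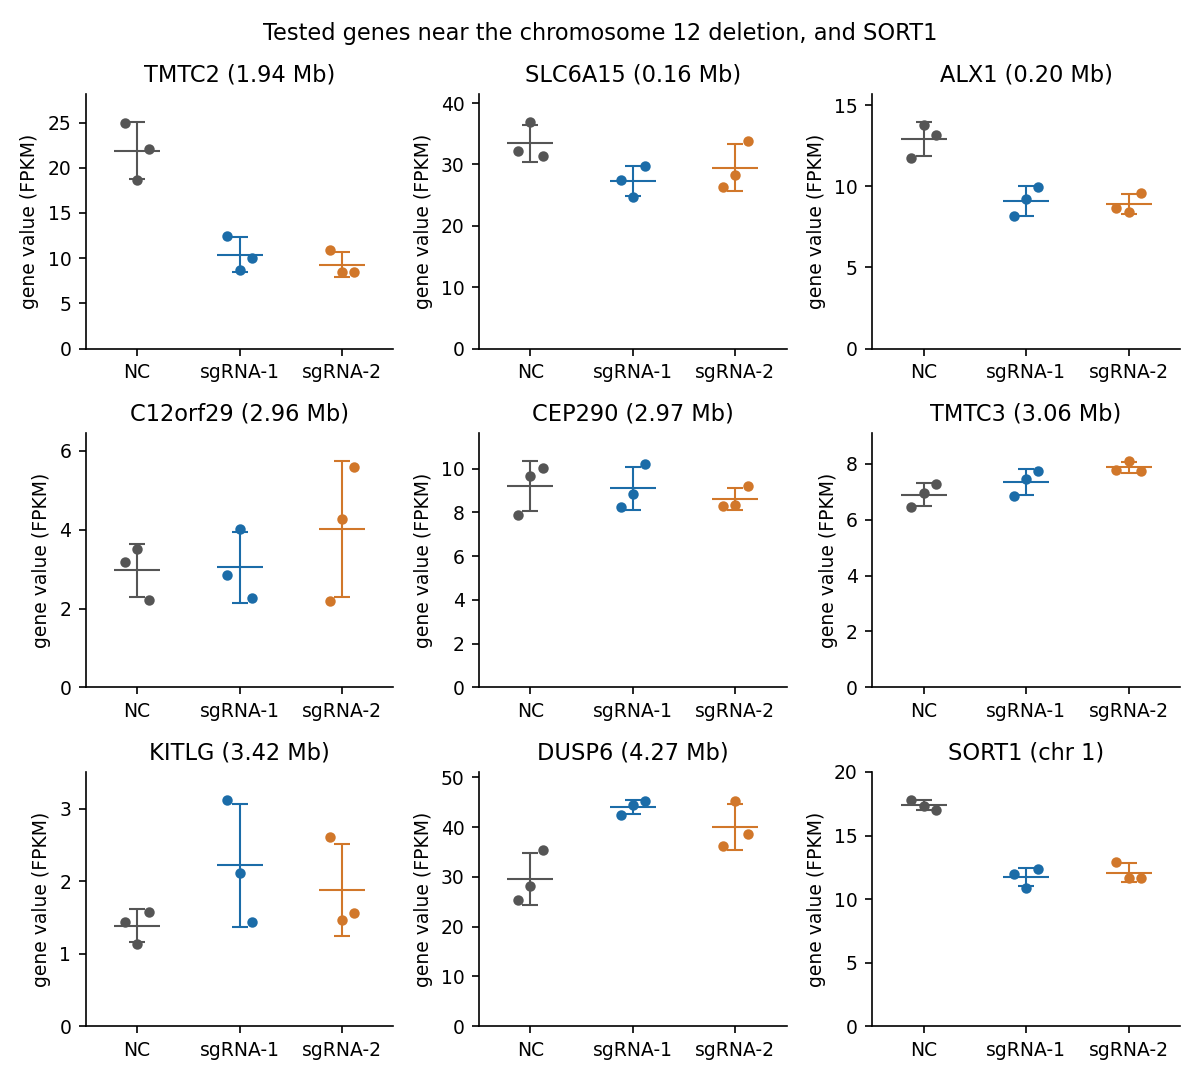
Gene values in FPKM of the 8 tested genes near the deletion, with their distance from it, and of SORT1 on chromosome 1, for the groups sgRNA-NC, sgRNA-1 and sgRNA-2. Points are libraries, and bars are the mean and SD of 3 libraries; TMTC2, ALX1 and SORT1 are lower and DUSP6 is higher in all guide libraries than in all control libraries.

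The comparison of sgRNA-1 with sgRNA-NC asks what changed in cells with the first guide. CD74, the invariant chain of MHC class II, went from 0.0522 ± 0.0904 to 37.6 ± 3.23 FPKM, a log2 fold change of 5.20 ± 0.09. HLA-DRA, an MHC class II chain, rose by 4.31 ± 0.09, and SFRP1, a secreted Wnt antagonist, by 4.71 ± 0.08. Further large rises were those of TUBB2B, a beta-tubulin that shares reads with its copies (4.45, uncertain), ARMCX1 (3.82), the homeobox gene HOXB2 (3.57), C10orf35 (3.02) and DKK1, another secreted Wnt antagonist (2.83). KCNMA1, a calcium-activated potassium channel gene, was listed at 0 in all control libraries and at 6.49, 6.48 and 6.57 FPKM with sgRNA-1. AC010441.1 rose by 3.10 ± 0.57 (adjusted p = 0.00421), with uneven values of 2.65, 12.5 and 12 FPKM. On this scale the largest fall was that of ITIH5, an inter-alpha-trypsin inhibitor heavy chain, from 31 ± 0.822 to 1.94 ± 0.196 FPKM (-3.44 ± 0.09). STAC3 fell by 3.32, LGI3 by 2.68, TMEM185B by 2.21, CRYL1 by 1.96, AZGP1 by 1.93, SLFN5 by 1.90 and GABRA5 by 1.90. With a pseudocount of 0.1 genes such as LGI3 (-5.49) and TMEM185B (-5.09) fell further than ITIH5 (-3.93). The melanocyte antigen gene MLANA fell by 1.97 ± 0.07 and TYRP1, a melanin synthesis enzyme, by 1.86 ± 0.11. Of 22 melanocyte genes 13 fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 2.8e-05, and adjusted p = 0.0882 with an estimated correlation), and of 13 dedifferentiated melanoma genes 8 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 1.4e-04, and adjusted p = 0.0882 with an estimated correlation). Limma called 3697 of 11063 genes, 2285 higher and 1412 lower, of which 310 rose and 139 fell by more than 2-fold. With quantile-normalized values 50.9% of calls were higher, against 61.8% here. For its most abundant transcript GABRA5 was not called (-1.22, adjusted p = 0.393), and 11 of 24 lists passed camera, the same as in both guides together and none with an estimated correlation, with the TGF-beta (0.0653) and oxidative phosphorylation (0.0925) lists lost without sgRNA-1 replicate 1. The oxidative phosphorylation list passed camera in only 13 of 24 alternatives. It was also lost without sgRNA-NC replicate 2 (0.0651) or sgRNA-NC replicate 3 (0.0615).

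In the comparison of sgRNA-2 with sgRNA-NC, which asks the same of the second guide, CD74 went from 0.0522 ± 0.0904 to 43.1 ± 0.501 FPKM (5.39 ± 0.09), and SFRP1 (4.82), TUBB2B (4.50), HLA-DRA (4.33), ARMCX1 (3.80) and HOXB2 (3.47) followed. KCNMA1 was at 7.29, 6.01 and 7.15 FPKM with sgRNA-2. NGFR, the nerve growth factor receptor, rose by 2.95 ± 0.13, the receptor tyrosine kinase AXL by 2.95 ± 0.13, and MGLL, which encodes monoacylglycerol lipase, by 2.91 ± 0.10. STAC3 fell by 3.23, ITIH5 by 3.21, LGI3 by 2.64, TMEM185B by 2.21, GABRA5 by 2.08 and CRYL1 by 2.07. Among pigment cell genes TYRP1 fell by 2.07 ± 0.11, MLANA by 2.06 ± 0.07 and DCT, dopachrome tautomerase, by 1.91 ± 0.07. TMSB4X, a thymosin gene, fell by 1.97 ± 0.27, but its listed values were low, at 3.13, 4.80 and 3.81 FPKM in the controls and at 0.930, 0 and 0 with sgRNA-2. AC010441.1 did not pass here (1.01 ± 0.57, adjusted p = 0.216), and its difference between the guides was not called. Of 22 melanocyte genes 12 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 1.6e-06, and adjusted p = 0.0473 with an estimated correlation), and of 13 dedifferentiated melanoma genes 9 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 9.0e-06, and adjusted p = 0.0473 with an estimated correlation). Limma called 3550 genes, 2141 higher and 1409 lower, of which 293 rose and 137 fell by more than 2-fold. With quantile-normalized values 49.7% of calls were higher, against 60.3% here. Of 24 lists 13 passed camera, and only the melanocyte and dedifferentiated melanoma lists passed with an estimated correlation. The G2/M list (camera adjusted p = 0.0377, and adjusted p = 0.262 with an estimated correlation) and the NF-kB list (0.0377 and 0.188) passed with this guide and not with sgRNA-1, and neither differed between the guides (camera adjusted p = 0.416 and 0.815). Without sgRNA-NC replicate 2 neither passed (0.0640 and 0.0641). Both were also lost with a batch term for replicate 1 (camera adjusted p = 0.0552 and 0.0634). Leaving out chromosomes 10, 13 and 18 gave 0.126 and 0.0961. Of 24 alternatives G2/M passed in 17 and NF-kB in 16.

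Both guides together, compared with sgRNA-NC, show what the guide libraries share. As lists, genes of pigment cells were lower, and genes of dedifferentiated melanoma, YAP/TAZ targets and antigen presentation were higher, at the preset correlation and not with an estimated one. NGFR went from 4.85 ± 0.627 FPKM to 39.1 ± 5.15 and 44.3 ± 5.21, a log2 fold change of 2.86 ± 0.11 (adjusted p = 1.2e-06). MLANA went from 75.5 ± 4.06 to 18.6 ± 1.5 and 17.3 ± 0.253 FPKM (-2.01 ± 0.06, adjusted p = 4.7e-07). Limma called 4212 genes (38.1%), 2559 higher and 1653 lower, of which 288 rose and 121 fell by more than 2-fold. Higher calls made up 60.8% of these, 50.2% with quantile-normalized values (2033 higher and 2014 lower) and 67.1% with values rescaled to the same total. The median of all genes was 0.06, and 0.11 after rescaling. By the naming rule, on this scale, the 10 largest rises were those of CD74 (5.29 ± 0.08), SFRP1 (4.77), TUBB2B (4.47), HLA-DRA (4.32), ARMCX1 (3.81), HOXB2 (3.52), KCNMA1, C10orf35 (2.92), NGFR and AXL (2.86). The 10 largest falls were those of ITIH5 (-3.33 ± 0.08), STAC3 (-3.28), LGI3 (-2.66), TMEM185B (-2.21), CRYL1 (-2.02), MLANA, GABRA5 (-1.99), TYRP1 (-1.97), AZGP1 (-1.89) and DCT (-1.85). For its most abundant transcript GABRA5 was not called (-1.35, adjusted p = 0.244; with sgRNA-2 -1.49, 0.294). KCNMA1 and C10orf35 lie in a part of chromosome 10 whose genes were higher as a group, and CRYL1 in the part of chromosome 13 whose genes were lower. ITIH5 and DCT lie on the same chromosomes outside these parts.

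Of 22 tested melanocyte lineage and pigment genes 14 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone. MLANA, TYRP1 and DCT led the falls, followed by CAPN3, a calcium-dependent protease gene (-0.98 ± 0.09). TYRP1 went from 194 ± 7.87 to 53.2 ± 7.75 and 45.5 ± 3.03 FPKM. MITF, the main transcription factor of this lineage and chosen after its values were seen, fell by 0.94 ± 0.10 (adjusted p = 1.7e-04). EDNRB, an endothelin receptor gene also chosen after its values were seen, was the member that rose (0.54 ± 0.17, adjusted p = 0.0362). Its call was lost without replicate 1 of every group (adjusted p = 0.135) and with quantile-normalized values (0.0625). The list was lower than other genes (camera adjusted p = 1.0e-05, and adjusted p = 0.0680 with an estimated correlation). In the same libraries mitochondrial transcripts made up 9.65% to 11.2% of the summed FPKM, against 12.1% to 13.6% in the controls.

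Of 13 tested genes of the dedifferentiated melanoma list 9 rose and 0 fell, with the same counts adjusted over the list alone. Next to NGFR and AXL these were led by TGFBI, a secreted matrix protein gene (2.58 ± 0.17), and JUN, a subunit of AP-1 (1.98 ± 0.08). The list was higher than other genes (camera adjusted p = 4.9e-05, and adjusted p = 0.0680 with an estimated correlation). Among 19 tested YAP/TAZ targets 14 rose and 1 fell, also when adjusted over the list alone. AXL, which this list shares with the preceding list, was followed by the matricellular genes CTGF (1.87 ± 0.07) and CYR61 (1.82 ± 0.05) and by ANKRD1 (1.80 ± 0.10), which lies on chromosome 10. FSTL1, a secreted glycoprotein gene chosen after its values were seen, was the member that fell (-1.19 ± 0.09). The YAP/TAZ list was higher than other genes (camera adjusted p = 3.3e-05, and adjusted p = 0.0693 with an estimated correlation). Of 16 tested TGF-beta response genes 11 rose and 3 fell, also when adjusted over the list alone. TGFBI, PMEPA1 (1.78), TGFB1, which encodes the ligand itself (1.71), and ID2, an inhibitor of DNA binding (1.22), rose most. The TGF-beta list passed with the preset correlation (camera adjusted p = 0.0140, and adjusted p = 0.361 with an estimated correlation), and not without genes that hold a transcript in 1 table only (camera adjusted p = 0.230), among them TGFBI, PMEPA1, TGFB1 and ID2.

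Antigen presentation genes rose in 10 of 18 tested cases, fell in 1 and did not pass in 7, with the same counts adjusted over the list alone. HLA-DRA went from 0.0738 ± 0.0406 to 20.3 ± 1.39 and 20.6 ± 1.70 FPKM. HLA-DRB1, another MHC class II chain, rose by 2.47 ± 0.13 and the class I gene HLA-B by 1.75 ± 0.09, and as members of a family with near-identical copies both are uncertain. PSMB10, an immunoproteasome subunit gene chosen after its values were seen, fell by 0.74 ± 0.12. The list was higher than other genes (camera adjusted p = 0.00486, and adjusted p = 0.145 with an estimated correlation). Both tested genes of the immune cell marker list, which has 16 genes, rose in the same libraries: FCER1G by 1.29 ± 0.27, from 0.793 ± 0.765 to 2.75 ± 0.838 and 3.50 ± 0.265 FPKM, and the lysosomal glycoprotein gene CD68 by 0.84 ± 0.12, from 1.61 ± 0.247 to 3.97 ± 0.528 and 3.42 ± 0.685 FPKM.

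Of 30 tested S phase and DNA replication genes 14 rose, 2 fell and 14 did not pass (15 higher and 3 lower adjusted over the list alone). Cyclin E1, CCNE1, rose by 1.10 ± 0.15, UHRF1, needed to maintain DNA methylation, by 1.05 ± 0.11, GINS3, of the replicative helicase, by 0.78 ± 0.07, and the transcription factor gene E2F1 by 0.73 ± 0.08. The S phase list passed with the preset correlation (camera adjusted p = 0.0167, and adjusted p = 0.195 with an estimated correlation), and not without genes that hold a transcript in 1 table only (camera adjusted p = 0.116). Among 15 tested immediate early and dissociation stress genes, a list fixed as a sign of sample handling and RNA quality, 8 rose and 1 fell (9 and 2 adjusted over the list alone). The leading members were JUN and genes of heat shock chaperones, HSPA1B (1.94 ± 0.06), HSPA1A (1.85 ± 0.05) and DNAJB1 (0.93 ± 0.06), of which HSPA1A and HSPA1B are near-identical and uncertain. The immediate early transcription factor gene EGR1 fell by 0.26 ± 0.05 and FOS did not pass (0.35 ± 0.16, adjusted p = 0.135), both chosen after their values were seen. The stress list was higher than other genes (camera adjusted p = 0.00522, and adjusted p = 0.361 with an estimated correlation), in the same libraries as the dedifferentiated melanoma and YAP/TAZ lists, and JUN belongs to the dedifferentiated melanoma list too.

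Ribosomal protein transcripts were lower: of 36 tested 24 fell and 0 rose (30 and 0 adjusted over the list alone). RPL4 fell by 0.67 ± 0.08, RPL5 by 0.54 ± 0.05, RPS28 by 0.54 ± 0.07 and RPL3 by 0.49 ± 0.06. The list took 4.79% to 5.16% of the summed FPKM in guide libraries and 5.81% to 5.87% in the controls (camera adjusted p = 5.8e-09, and adjusted p = 0.195 with an estimated correlation). Its median log2 fold change was -0.29, and -0.18 with 13 falls in quantile-normalized values. Of 13 transcripts of the mitochondrial genome 11 fell and 0 rose (12 and 0 adjusted over the list alone), by a median of -0.36, and by -0.31 with 11 lower after rescaling. This list was fixed in advance as a sign of RNA quality. MT-ND5 fell by 0.88 ± 0.05, MT-ATP8 by 0.50, MT-ATP6, which overlaps it, by 0.45 and MT-CYB by 0.42. The mitochondrial list passed (camera adjusted p = 2.8e-05, and adjusted p = 0.361 with an estimated correlation), and quantile normalization cannot test it, since most of these transcripts rank at the top of every library and are set to nearly equal values. Nuclear genes of oxidative phosphorylation fell in 6 of 31 cases and rose in 1, also when adjusted over the list alone. UQCRC2 (-0.68) and UQCRC1 (-0.45) of complex III and NDUFV2 (-0.47) of complex I, on chromosome 18, fell, and NDUFB8, on chromosome 10, rose (0.35), NDUFV2 and NDUFB8 each in the direction of its chromosome's median. The oxidative phosphorylation list passed (camera adjusted p = 0.0164, and adjusted p = 0.275 with an estimated correlation), and not after quantile normalization (camera adjusted p = 0.0665).

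Of 25 tested genes of the ATF4 and unfolded protein response 12 fell, 2 rose and 11 did not pass, with the same counts adjusted over the list alone. PHGDH, an enzyme gene of serine synthesis, fell by 1.22 ± 0.18, CHAC1, a glutathione-degrading enzyme gene, by 1.08 ± 0.13, MTHFD2, of mitochondrial folate metabolism, by 0.51 ± 0.15, and ATF4 itself by 0.47 ± 0.04. The most abundant transcript of PHGDH did not pass by itself (-0.07, adjusted p = 0.962). The list was lower than other genes (camera adjusted p = 0.00222, and adjusted p = 0.0680 with an estimated correlation). Of 24 lists 11 passed in both guides together, 6 upward and 5 downward, and none did so with an estimated correlation. Without sgRNA-NC replicate 2 the calls of EDNRB (adjusted p = 0.115), MTHFD2 (0.0695) and MT-ATP8 (0.0882) were lost, and without sgRNA-1 replicate 2 FOS passed (0.0431). The most abundant transcripts of MITF (-1.40, adjusted p = 0.196), UHRF1 (0.67, 0.730), PMEPA1 (0.85, 0.369) and ID2 (0.91, 0.514), among others, did not pass by themselves.

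**Figure D2:**
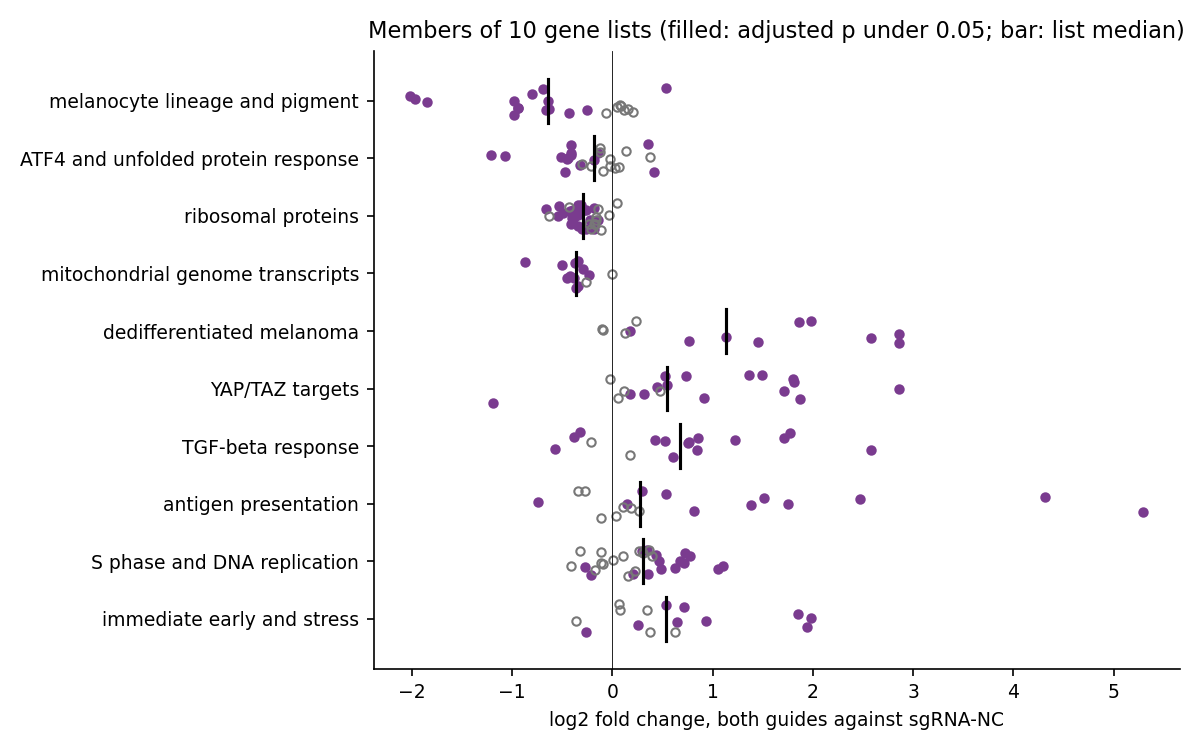
Log2 fold changes, both guides against sgRNA-NC, of the tested members of 10 gene lists. Each point is a gene, filled where its adjusted p is under 0.05, and the bar is the list median, such as -0.64 for melanocyte genes and 1.13 for dedifferentiated melanoma genes.

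Largely the same genes differed from the controls with both guides. Of the calls 1838 were higher with both and 1136 lower with both, against 442 and 180 in independent lists of these sizes, and 0 were called in opposite directions. Limma called 2974 genes with both guides, and 15 genes were named in both comparisons, among them CD74, SFRP1, HLA-DRA, ITIH5, STAC3 and MLANA. Across genes, Pearson's r of the log2 fold changes was 0.893 and Spearman's rho 0.867, where 100 simulated draws of unchanged groups with shared controls gave a mean r of 0.50 (0.460 to 0.539). Genes of the same sign made up 86.4%, against 66.7% simulated, and the covariance was 0.215 against 0.0239, a difference of 0.191. In these draws 0.02 genes on average, and at most 1, were called with both. Part of the excess over independent lists may come from the 3 shared controls, which are too few to be split. A single difference between the control cells and the cells of both guides could give the same overlap. The overlap cannot tell such a difference from an effect of the deletion.

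**Figure D3:**
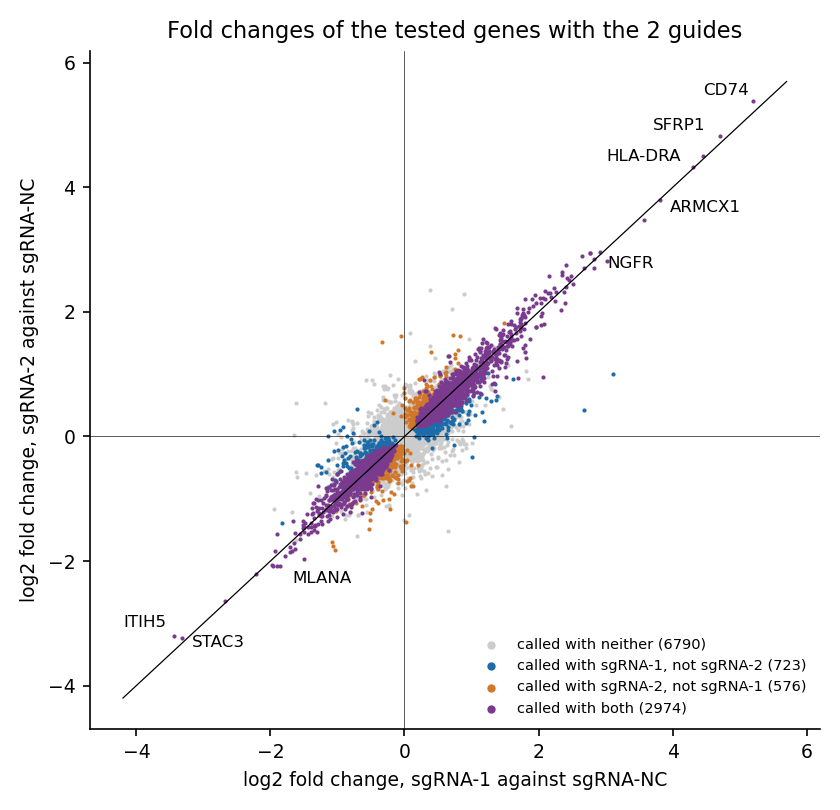
Log2 fold changes of 11063 genes with sgRNA-1 (x axis) and sgRNA-2 (y axis), each against sgRNA-NC, coloured by whether limma called the gene with both guides, either or neither. The line marks equal changes, and the 2974 genes called with both lie along it, from ITIH5 and STAC3 to CD74.

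The comparison of sgRNA-2 with sgRNA-1 asks whether the guides differ. MB, the myoglobin gene, was the single gene called: its values were 2.26, 3.50 and 2.28 FPKM with sgRNA-2, it is not listed for sgRNA-1, where its values were set to 0, and the control libraries had 0.296, 0.108 and 0.405 FPKM (adjusted p = 0.0180). The call was lost with missing values at 0.5 FPKM (adjusted p = 0.225), in a fit of the 6 libraries compared (0.0779), without sgRNA-NC replicate 3 (0.0595) and without sgRNA-1 replicate 1 (0.0843). At an unadjusted p under 0.05 there were 766 genes, against 553 by chance. Of the 2974 genes called with both guides, 2961 (99.6%) had a 95% interval of the guide difference within 1 log2 unit of 0, as had 90.5% of all genes tested. The bound is wide: of 3697 genes called with sgRNA-1, 310 rose and 139 fell by more than 2-fold, which is 1 log2 unit. Genes called with both guides were also chosen for passing with each, so these shares do not show that smaller changes agree. YAP/TAZ targets as a list were higher with sgRNA-2 (median difference 0.12, camera adjusted p = 0.00346, and adjusted p = 0.494 with an estimated correlation), with none of its 19 members called and 2 higher adjusted over the list alone.

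Gene changes were not even along the genome, a feature singled out after the values were seen. Relative to all genes the median log2 fold change in both guides was 0.32 on chromosome 10 (420 genes), -0.31 on chromosome 13 (187 genes) and -0.34 on chromosome 18 (156 genes). Unadjusted medians were 0.38, -0.24 and -0.28, and 0.22 on chromosome 14 and 0.18 on chromosome 4. With the genes of a chromosome split by position into 4 parts of nearly equal gene number, the relative medians along chromosome 10 were 0.10, 0.46, 0.31 and 0.35. Along chromosome 13 they were -0.55 and -0.48 up to position 49867621, and -0.09 and 0.04 beyond, and along chromosome 18 -0.46, -0.19, -0.30 and -0.20. Without these 3 chromosomes limma called 3723 genes in both guides together.

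**Figure D4:**
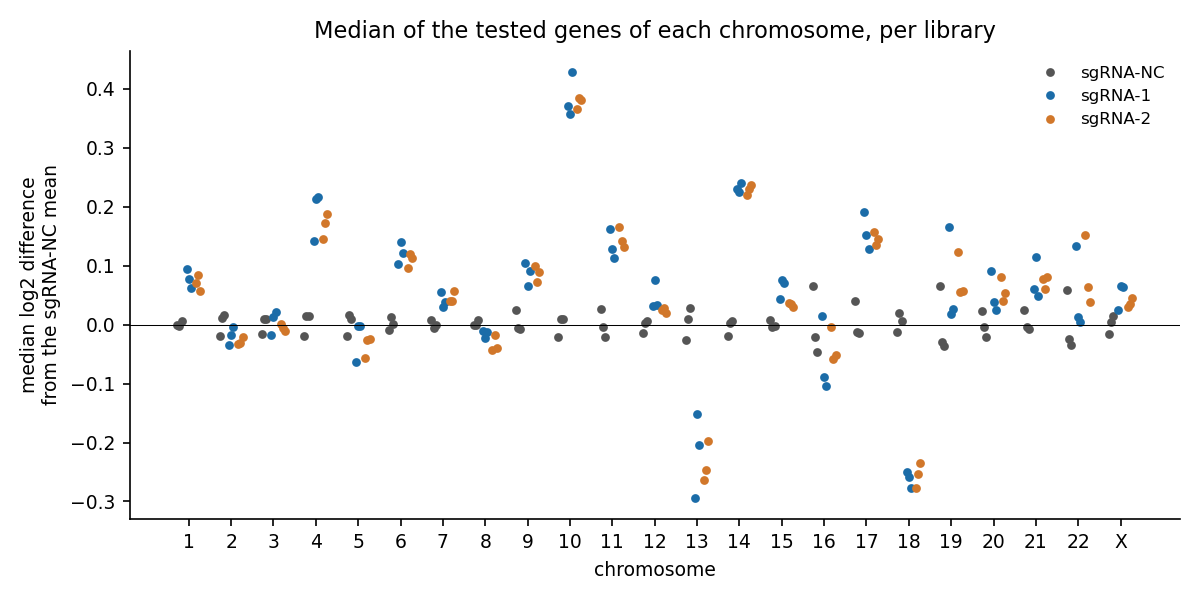
Median over the tested genes of each chromosome of the log2 difference from the sgRNA-NC mean, a point per library, for sgRNA-NC, sgRNA-1 and sgRNA-2. All guide libraries lie above all control libraries on chromosome 10 and below them on chromosomes 13 and 18.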

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

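The tests in this part were planned, but MB and the lists are singled out because they differed between the guides. Groups of 3 libraries are too small for a search for outlying samples, so the results here come from the test of sgRNA-2 against sgRNA-1.

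MB, the myoglobin gene, differed by a log2 fold change of 1.86, a value that rests on its absence from the sgRNA-1 table, since the transcript was set to 0 there; with missing values at 0.5 FPKM it was 0.86 and not called. The dedifferentiated melanoma list was higher with sgRNA-2 (camera adjusted p = 0.0382, and adjusted p = 0.494 with an estimated correlation). The YAP/TAZ targets were higher with sgRNA-2 (camera adjusted p = 0.00346, and adjusted p = 0.494 with an estimated correlation). The TGF-beta response list was higher with sgRNA-2 (camera adjusted p = 0.0304, and adjusted p = 0.618 with an estimated correlation). The replication-dependent histone list, fixed as a sign of RNA selection, was higher with sgRNA-2 (camera adjusted p = 0.0407, and adjusted p = 0.558 with an estimated correlation). The immediate early and stress list was lower with sgRNA-2 (camera adjusted p = 0.0304, and adjusted p = 0.618 with an estimated correlation). No gene of these lists was called over all genes, and adjusted over the list alone 2, 2, 2 and 0 genes were higher and 3 stress genes lower. Their median differences were 0.12, 0.12, 0.10, 0.25 and -0.10 in this order, and the YAP/TAZ list passed in 23 of 24 alternatives at the preset correlation, the others in 17, 17, 12 of 23 and 16.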

How the results depend on the processing

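The alternatives added after seeing the data are sums over shared transcripts only, missing values at 0.5 FPKM, and the fits without chromosomes 10, 13 and 18 or without genes holding a transcript in 1 table only. The handling of missing transcripts was itself chosen after seeing the data. With shared transcripts only, limma called 3575, 3409, 1 and 4105 genes (sgRNA-1, sgRNA-2, sgRNA-2 against sgRNA-1, both guides). The single gene was then SLBP, lower with sgRNA-2, not MB, and SLBP is named here after its values were seen. Replicate numbers carried some shared structure, mainly in replicate 1, which the main fit leaves out. Deviations of same-numbered libraries correlated at 0.15 to 0.23 in replicate 1 and 0.01 to 0.10 in replicates 2 and 3. Of 9 libraries 5 correlated best with their own number. With the replicate block 4457, 4347, 0 and 4973 genes were called, and the G2/M (camera adjusted p = 0.0614) and NF-kB (0.0642) lists no longer passed with sgRNA-2, nor was MB called between the guides (adjusted p = 0.175). Replicates 2 and 3 alone gave 3600, 3511, 7 and 4165 genes, and 3972 of the 4165 (95.4%) had the same sign in replicate 1 alone. A batch term gave 4657, 4600, 5 and 5166.

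The difference between the guides gave 89 genes with no filter, 0 with a filter of 5 FPKM, 22 for transcripts, 118 after rescaling, 2 after quantile normalization, 0 in a fit of 6 libraries, 0 with missing values at 0.5 FPKM and 0 without genes holding a transcript in 1 table only. Genes holding a filled transcript were 77 of the 89 and 103 of the 118. Rescaling raised all values while the filter and the pseudocount stayed the same, so it also loosened the filter and let lower genes in. The count after rescaling is therefore not that of a changed total alone. How much each of these steps moved the counts was not tested. Transcripts in place of genes gave 2314 and 2265 calls for sgRNA-1 and sgRNA-2, 1745 of them shared, and the deposited q-values 1554 and 1573, 937 shared. At an adjusted p under 0.01 the guides shared 1735 genes. Lists passing with an estimated correlation numbered 0, 2, 0 and 0, and lists differing between the guides 1 with a pseudocount of 0.1, 2 with shared transcripts only and 1 without genes holding a transcript in 1 table only. Leaving out each library in turn gave 2842 to 3687, 2685 to 3691, 0 to 5 and 3252 to 4232 genes, 2277 to 2762 shared by the guides, and 9 to 11, 11 to 13, 2 to 5 and 11 to 12 lists.

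Of 183 results on named genes 167 were called, and 112 of these kept call and direction in every alternative that tested them. Not every alternative tested each result. The filter of 5 FPKM left 152 results, and leaving out genes holding a transcript in 1 table only left 151. No call reversed. Some values that were not called turned. CEP290 with sgRNA-1 (-0.01) turned to 0.03 after rescaling, and ranged from -0.109 to 0.0475 when leaving out each library in turn, with 0.0217, 0.0466 and 0.0028 without sgRNA-NC replicate 2, sgRNA-NC replicate 3 and sgRNA-1 replicate 2. CEP290 in both guides (-0.05) ranged from -0.143 to 0.0128. C12orf29 with sgRNA-1 (0.02) turned to -0.0561 after quantile normalization and ranged from -0.148 to 0.164, with -0.124 without sgRNA-NC replicate 3. TMTC3 with sgRNA-1 (0.08) turned to -0.0056 after quantile normalization; the cause was not tested. Depth is unknown, so what it limits cannot be given.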

Other observations

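The patterns on chromosomes, ribosomal proteins and SLC6A15 were picked after the data were seen, and the tests of random gene placement and of reads reassigned between SLC6A15 transcripts were chosen after the result was seen, the others before. In both guides together, some members of several lists changed strongly although the lists as a whole did not pass. Of all 11063 tested genes 38.1% were called, 2559 higher and 1653 lower. Member counts near these shares are no result about a list. Of the MAPK output genes 9 of 19 rose and 5 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.260), with rises of LIF, a cytokine of the interleukin 6 family (2.50), the phosphatase gene DUSP5 on chromosome 10 (1.60), PHLDA1 (1.44) and cyclin D1, CCND1 (1.41). Among matrix and mesenchymal genes 7 of 21 rose and 4 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.551): THBS1, thrombospondin 1 (2.30), FN1, fibronectin (2.22), and the collagenase gene MMP1 (0.74) rose, and the integrin gene ITGB3 fell (-1.25). Of the NF-kB genes 6 of 13 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0599), with rises of LIF, of TNFAIP3, an inhibitor of this pathway (1.63), and of NFKB2 on chromosome 10 (0.88), and a fall of the cyclooxygenase gene PTGS2 (-1.35). Of p53 targets 6 of 21 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.620), with 3 higher and 4 lower in quantile-normalized values, led by PHLDA3 (2.09), the cell cycle inhibitor gene CDKN1A (1.20) and AEN (0.70). In the G2/M list 9 of 28 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0599), with AURKB (0.74), CDK1 (0.73), KIF11 (0.52) and CDC20 (0.52) higher, CDK1 and KIF11 on chromosome 10, and the list passed without sgRNA-NC replicate 1 (0.0460) or sgRNA-2 replicate 1 (0.0398). Of interferon response genes 7 of 19 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.526), with BST2, tetherin (1.54), IFI44 (0.56) and HERC5 (0.52) higher.

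Of CTCF and cohesin genes 5 of 12 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.260): SMC3 (0.59) and WAPL (0.56), both on chromosome 10, and PDS5A (0.37) rose and MAU2 fell (-0.49). CTCF itself, chosen after its values were seen, rose by 0.19 ± 0.05 (adjusted p = 0.0217), a call lost with quantile-normalized values (0.112) and without sgRNA-NC replicate 1 (0.0693). Of hypoxia and glycolysis genes 7 of 22 rose and 6 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.991), with rises of the glucose transporter gene SLC2A1 (1.36) and of ADM (0.98) and a fall of VEGFA (-0.97), but 5 rose and 6 fell with quantile-normalized values. Of cholesterol synthesis genes 2 of 21 rose and 6 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.329), with falls of the regulator gene SREBF2 (-0.98), FDFT1 (-0.57), DHCR7 (-0.50) and LSS (-0.48), and a median of 0.01 beside a mean of -0.11, but 5 rose and 5 fell of 23 after rescaling. Of apoptosis genes 7 of 19 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.697), with BMF (0.70) and BCL2L1 (0.62) higher, HRK lower (-0.63), and a median of -0.02 beside a mean of 0.07, but 6 rose and 5 fell with quantile-normalized values. Of histone genes 3 of 10 rose and 0 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.765), HIST1H2BC (0.71) and HIST1H1C (0.60) among them, uncertain as members of near-identical families, but 1 rose and 2 fell with quantile-normalized values. The histone list was fixed as a sign of how RNA was selected for the libraries. Of genes higher in class 1 uveal melanoma 2 of 7 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.956), ID2 and LMCD1 (0.97), with a median of -0.07 and a mean of 0.25, and of the 3 tested of class 2 ECM1 rose (0.81). Lists with under 5 tested members were not tested as lists. Among retinal pigment epithelium markers SERPINF1 rose (1.62) and BEST1 (-0.55) and RLBP1 (-0.39) fell. Among photoreceptor markers RXRG fell (-0.99) and GNGT1 rose (0.50, a rise not called with quantile-normalized values). The call of GNGT1 was also lost with the replicate block (adjusted p = 0.0743) and without replicate 1 of every group (0.1985). The endothelial marker ERG rose (0.72, not called with quantile-normalized values), the fibroblast marker LUM fell (-0.87), the epithelial gene ESRP1 fell (-0.36), and of 8 erythroid markers 0 were tested. Without sgRNA-NC replicate 2 the calls of PHLDA1 (adjusted p = 0.0552), VEGFA (0.0853), LSS (0.0526), HIST1H2BC (0.0872), GNGT1 (0.148), ERG (0.0701) and ESRP1 (0.0572) were lost, without replicate 3 that of LMCD1 (0.0573) and without replicate 1 that of RLBP1 (0.0552). The most abundant transcripts of BCL2L1 (0.22), WAPL (0.26) and FDFT1 (-0.26) did not pass by themselves. Nor, among others, did those of AURKB, CDK1, CDKN1A, ADM, VEGFA, SREBF2, DHCR7, LSS, BMF, LMCD1, RXRG and RLBP1.

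Other splits of the libraries tested whether an arbitrary division of the samples gives as many calls. For both guides against sgRNA-NC, 1 of 84 splits, the real one, gave as many genes (4250, highest other 3), so arbitrary divisions did not reach the count. Every other split mixes control and guide libraries, which the first principal component already separates, so the test adds little to that separation. It also cannot speak to libraries of a group that share a culture. For sgRNA-1 against sgRNA-NC 1 of 10 splits gave as many (3249, highest other 6) and for sgRNA-2 1 of 10 (3303, highest other 3), and 10 splits are too few for a share under 0.05. For sgRNA-2 against sgRNA-1 10 of 10 splits gave as many (0 in the real split, 13 in the highest other), which any split must where the real count is 0, so this cannot tell.

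By their medians, genes of chromosome 10 were shifted up and those of chromosomes 13 and 18 down in both guides, on chromosome 13 only up to position 49867621 (-0.09 and 0.04 in the parts beyond) and on chromosome 10 little before position 47222824 (0.10). Random placement of the genes gave a p of 1e-04, the smallest that 10000 placements can give, and after a trend with GC content and transcript length was removed the smallest of the 3 shifts was still 0.309 in size, which argues against both as the whole cause. A difference in copy number between guide and control cells, of only parts of chromosomes 10 and 13, is a candidate explanation: at least 72.2% of the genes of each chromosome lay on the shifted side, and the shift held in genes of low, middle and high level. The chromosomes were picked for their medians, so a majority of genes on the shifted side was fixed beforehand. These values also cannot tell copy number from another effect spread over a chromosome. Copy number stays a hypothesis, since no DNA data were used here, and a biological effect of the deletion on these chromosomes was not tested.

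Ribosomal protein transcripts were lower in both guides, as a list at the preset correlation and not with an estimated one (adjusted p = 0.195). With the trend in GC content and transcript length removed the list's median relative to all genes was -0.336, which argues against length and GC as the whole cause. The median was -0.416 in replicate 1 alone and -0.315 in replicates 2 and 3, so the fall did not rest on 1 batch. A batch shift alike in all 3 groups cancels in this comparison by design, so these values are no test of it. Whether library scaling accounts for part of it cannot be told. With quantile-normalized values the median was -0.179, between the bounds set in advance, but that step also reshapes the values of abundant transcripts. Rescaling to a total moves all genes nearly alike (-0.353) and cannot test this. An effect of the deletion stays open and was not tested.

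SLC6A15-201 fell and SLC6A15-202 rose in the guides. Reads reassigned between the transcripts by the quantifier may contribute, since the share of SLC6A15-202 ranged over 0.612 within the sgRNA-1 libraries while the sum of both changed little. Against this, the share ranged over only 0.0875 within sgRNA-2 and 0.00126 within the controls. Swings in isoform share are common here: 23% of genes with several listed transcripts and at least 5 FPKM have a transcript whose share ranges over more than 0.5 within a group. A change of promoter or splicing near the deletion stays open and was not tested.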
